A study of Homo sapiens with 6 samples.

How the data were processed

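RNA of A549 cells, an established human lung adenocarcinoma line, was measured on 6 Illumina Human-6 bead arrays, 3 from control cells and 3 from cells given DAMTC at 160 µg/ml for 24 h. Arrays were assigned to the 2 groups from their sample titles. DAMTC is used here as the code name the labels give, and the vehicle of the control cells is not given in the sources used here. The labels call the triplicates biological without naming separate cultures, so p-values measure the spread between these arrays. All 6 arrays lay on 1 BeadChip, with the control arrays in its first positions and the DAMTC arrays in its last, so position and group cannot be told apart.

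The deposited non-normalized table gives, per the file headers, a mean bead intensity for each probe and array on a linear scale, which was neither background-subtracted nor scaled between arrays. Per the file headers it also gives a detection p-value, and its values move in steps of 1/759, so 759 negative-control bead types stand behind it. The number of beads and their standard error are other deposited columns of the same table. BeadStudio is named as the software per the submitters' processing notes, with its version not given in the sources used here. The deposited series matrix intensity values were set against the same arrays' bead intensities. Each column was a straight line of them, with a largest residual of 0.0107, after subtraction of an offset between 118.95 and 140.6 and scaling to an array mean between 461.96 and 462.07. The column medians were 10.94, 9.339 and 8.585 for control replicates 1 to 3 and 8.992, 8.696 and 9.167 for DAMTC replicates 1 to 3. Scale, centring and direction of that table are therefore known, and it was used as an alternative.

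Intensities were background-corrected with nec of limma 3.58.1 in R 4.3.3, with the background taken from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. Of 48803 probes, 27578 had 1 gene symbol in the platform annotation, 13 had several and 21212 were not listed there and stay unnamed. Entrez IDs of 27541 probes were found in the RefSeq gene table of GRCh38.p14, used for names only, and 0 symbols changed. 1 probe ID that stood on a pair of rows was averaged. Probes were kept if detected at p under 0.05 on at least 3 of the 6 arrays and listed with 1 symbol, and each gene was represented by its kept probe of highest mean level. This left 10779 genes, while 7886 genes were too dim to be tested. Among genes that changed, 690 of 768 further probes moved in the same direction as the chosen one and 78 in the opposite direction, 6 of these past the threshold.

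DAMTC was compared with control by lmFit and eBayes, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no replicate block. Where a probe was not detected on any array of a group, the fold is a bound, written "at least", of the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own value. 38 gene lists were fixed before the data were examined, and the 36 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with fry beside it. Camera sets a list against all other genes, while fry asks whether its members changed at all. A list can therefore pass fry without shifting more than other genes. Of 1144 list entries, 1048 were on the array. 1 tested list that did not pass, and 4 genes named only for it, are not reported here. Genes were named by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes past the threshold. These had to separate the groups completely, be detected on all 3 arrays of the higher group and carry no provisional symbol. It also takes, per list, up to 4 members past the threshold with the largest difference, or else the member of smallest p. GAPDH, ACTB, B2M, CDKN1A, HMOX1, DDIT3, CYP1A1 and CALR were named in any case. Other list members are named where a count is spelled out, and were then chosen after their values were seen.

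Counts of list members are also given where they moved by at least 2 members and by more than 1.5 times without 1 array or under another background or scaling. Alternatives covered the background correction, the normalization, the deposited series matrix values, the detection filter, the probe rule, the moderation of variances, array weights, a replicate block, each array left out in turn, the threshold and the set test. The whole path was tested on simulated intensities of DAMTC against control, with the real probes' levels and spread and 200 genes changed. Over 12093 simulated genes, 0% of 64 genes changed by 1.5-fold, 3.12% of 64 changed by 2-fold and 67.8% of 59 changed by 4-fold were recovered, and 0% of the calls were false. Benjamini-Hochberg adjustment is stricter when fewer genes change, and in the real comparison 2689 of 10779 genes passed. These recovery rates therefore do not carry over to it. The fitted median log2 differences were 0.59, 1.02 and 1.97 where 0.58, 1 and 2 had been put in. With no gene changed, limma called 0 genes (614 at an unadjusted p under 0.05) and camera 0 lists. With the members of 1 list raised by 1 on the log2 scale, camera called 2 lists, the other sharing 2 raised members, and the raised list had adjusted p = 0.00344 with an estimated correlation. Probes were simulated independently of each other, while the estimated correlation of a real list reached 0.8859. The simulated list results therefore do not show how often camera calls lists falsely in the real data. Tables were read with the R package data.table, version 1.17.8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.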

Results

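The series set A549 lung adenocarcinoma cells exposed to DAMTC against control cells to find the genes whose transcript levels differ after treatment. The 3 control arrays had 17357, 17364 and 17835 probes detected above background, and the 3 DAMTC arrays had 16622, 17058 and 16329. The means were 17519 ± 274 and 16670 ± 367 probes (SD, n = 3), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Mean bead intensity ranged from 528 to 673 over the arrays, with a median of 36 to 38 beads per probe. On the first principal component, which held 62.4% of the variance, the groups separated. On the second, with 22.9%, control replicate 1 lay at 56.5 and the other controls at -36.0 and -19.5.

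With DAMTC, the median log2 difference was positive over a list of glycolysis and hypoxia genes and negative over lists of ER chaperones and of targets of ATF4, the transcription factor of the amino acid and ER stress response. The set tests of these lists passed with a preset inter-gene correlation and not with an estimated one (adjusted p = 0.114, 0.667 and 0.402 with an estimated correlation). The estimates were 0.0238, 0.1802 and 0.02, against a preset of 0.01. Without control replicate 2 the estimate for the glycolysis and hypoxia list was 0.0065, and camera gave adjusted p = 0.183 with it against 5.6e-11. Without DAMTC replicate 2 that for ATF4 targets was -0.013, with adjusted p = 0.427 against 0.00318. In these fits the estimate lay below the preset, so the size of the correlation alone does not account for the lost calls. With an estimated correlation camera takes its degrees of freedom from the few arrays, and with a preset one from the number of genes. Loss of a call with an estimated correlation is therefore no sign by itself of correlated members. ALDOC, a glycolytic aldolase, rose 75.3-fold (log2 difference 6.23 ± 0.27 SE, n = 3 per group, adjusted p = 2.74e-05), and HK2, a hexokinase, rose 53.9-fold (5.75 ± 0.48, adjusted p = 2.19e-04) and 81.3-fold without control replicate 1. TCIM fell 63.8-fold (adjusted p = 2.74e-05), and HSPA5, the main HSP70 chaperone of the ER, fell (log2 difference -3.32 ± 0.58, adjusted p = 0.00432). IL6, an inflammatory cytokine, fell 24.8-fold (-4.63 ± 0.56, adjusted p = 9.06e-04) and was detected on 1 of the 3 DAMTC arrays. Its fall was 14.8-fold without control replicate 1 and 21.6-fold with DAMTC values set to no less than each array's lowest detected signal, an alternative chosen after seeing the data.

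Of 10779 genes tested, 2689 (24.95%) changed, 1311 higher and 1378 lower with DAMTC, and 1108 and 1181 of these by at least 2-fold. The groups did not overlap for 4520 genes (41.93%), where chance gives 10%. With arrays scaled to the same median in place of quantile normalization, 29.5% of the changed genes were higher against 48.8%, and with the deposited background-subtracted values 36.1% were. These scalings put the median log2 difference of all genes at -0.26 and -0.19, against -0.04. The number of changed genes was 1619, 1637 and 1582 without DAMTC replicate 1, 2 and 3, and 3696 without control replicate 1.

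The other genes among the 12 largest rises were NRIP3 (35.4-fold), CDKN2D (31.9-fold), KHDRBS3 (31.6-fold), EFNB2 (28.1-fold), SPINK1 (at least 21.3-fold), KBTBD8 (23.6-fold), RORA (22.7-fold), SERTAD1 (22.6-fold), TENT5C (19.2-fold) and PKIA (19.0-fold). CDKN2D encodes an inhibitor of the cyclin D kinases, EFNB2 the ligand ephrin-B2, and PKIA an inhibitor of protein kinase A. SPINK1 was not detected on any control array (4.95 ± 0.10 against 9.68 ± 0.56, log2, SD). KBTBD8 was detected on 2 of 3 control arrays and RORA and TENT5C on 1. With control values set to no less than each array's lowest detected signal, an alternative chosen after seeing the data, their folds were 21.5, 18.8 and 17.4. The other large falls were LURAP1L (at least 22.6-fold), PCED1B (23.7-fold), AJUBA (19.6-fold), PDE4B (17.9-fold), PRDM1 (16.6-fold), IGFBP1 (15.6-fold), PDE4D (15.5-fold), SMAD6 (14.9-fold), HKDC1 (14.6-fold) and TSKU (14.1-fold). PDE4B and PDE4D encode phosphodiesterases that degrade cyclic AMP. LURAP1L was not detected on any DAMTC array (9.84 ± 0.55 in controls against 4.76 ± 0.04). AJUBA was detected on 1 of 3 DAMTC arrays and PDE4D on 2. With DAMTC values set in the same way their folds were 18.5 and 14.1. Adjusted p ranged up to 0.00383 over these 24 genes, and each stayed past the threshold in all 6 fits that left out 1 array. The fold of IGFBP1 was 10.1 without control replicate 2 and 23.7 without DAMTC replicate 3, and that of PDE4D was 10.2 without control replicate 1. A second PDE4B probe read -1.10 on the log2 scale and further PRDM1 probes read -3.06 (adjusted p = 7.73e-04) and -0.39 (adjusted p = 0.297). The further RORA probes read from 0.48 (adjusted p = 0.191) to 4.92.

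**Figure D1:**
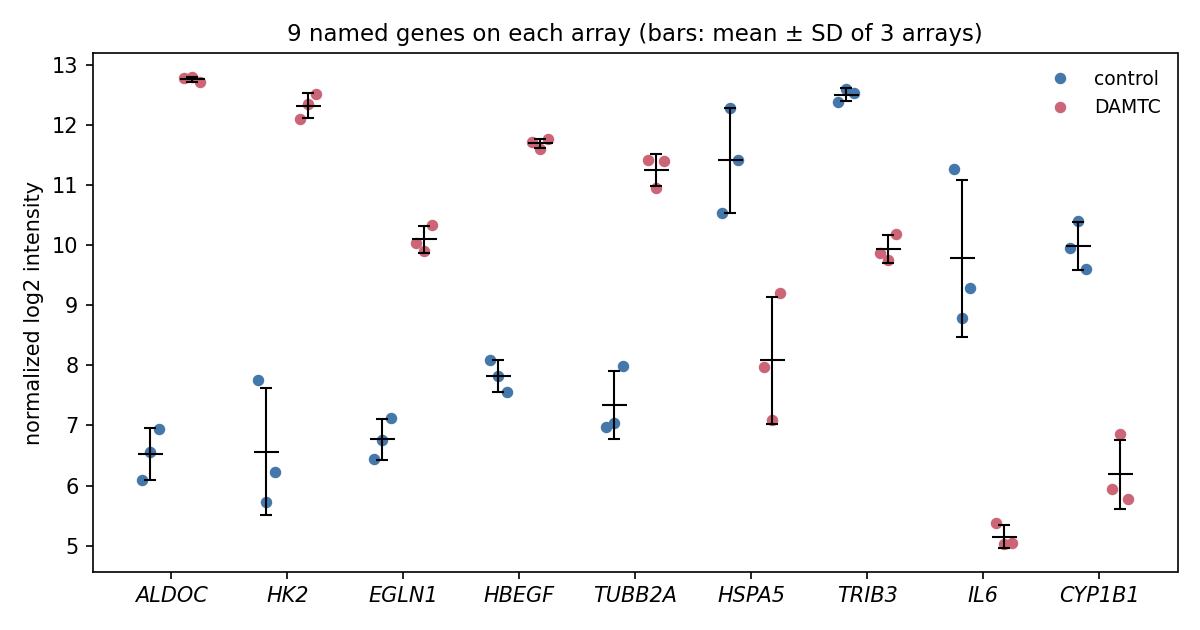
Normalized log2 intensity (vertical axis) of 9 named genes on each of the 6 arrays, control in blue and DAMTC in red, with black bars for the mean ± SD of 3 arrays. ALDOC lies near 12.8 with DAMTC and 6.5 in controls, and the arrays of IL6 spread widely in controls (SD 1.31).

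Among 34 measured glycolysis and hypoxia genes, 23 rose, 0 fell and 11 did not pass (24 rose adjusted over the list alone), with a median log2 difference of 1.49. Camera gave adjusted p = 8.06e-12 with the preset correlation and adjusted p = 0.114 with an estimated correlation. Besides ALDOC and HK2, ANKRD37 rose 10.5-fold (3.39 ± 0.35) and EGLN1, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation, rose by 3.32 ± 0.27. PGK1 rose 3.45-fold (1.78 ± 0.38), and a second PGK1 probe read 0.81 (adjusted p = 0.0644).

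Among 23 measured ER chaperone and unfolded protein response genes, 9 fell, 2 rose and 12 did not pass (10 and 2 adjusted over the list alone), with a median of -0.75 and camera adjusted p = 0.0299, adjusted p = 0.667 with an estimated correlation. CRELD2 (-2.74 ± 0.75, adjusted p = 0.0290) and HYOU1 (-2.00 ± 0.58, adjusted p = 0.0368) fell with HSPA5, while ERO1A, an ER oxidase, rose (1.86 ± 0.25, adjusted p = 0.00129). CRELD2 differed by -3.40 without control replicate 1 and -3.56 without DAMTC replicate 3, HYOU1 by -2.60 without control replicate 1, and a second HYOU1 probe read -1.63 (adjusted p = 0.0864). The list's call was lost without DAMTC replicate 1 (adjusted p = 0.0636), without DAMTC replicate 2 (adjusted p = 0.0782), with fry (0.0951) and with detection on all 6 arrays (0.0557), within a range of 0.00203 to 0.667 over 19 alternatives. The falls numbered 4 and 5 without control replicate 2 and 3, and 3 without DAMTC replicate 1 or 2. Among 30 measured ATF4 targets, 11 fell, 2 rose and 17 did not pass (16 and 3 over the list alone), with a median of -0.94 and camera adjusted p = 0.00112, adjusted p = 0.402 with an estimated correlation. Of these targets, 18 fell without control replicate 1, 18 with median scaling and 15 with the deposited values, and no rise passed without control replicate 3 or DAMTC replicate 1 or 3. TRIB3 fell 5.94-fold (-2.57 ± 0.24), SLC7A11, the cystine transporter, 4.66-fold (-2.22 ± 0.30), WARS1 4.49-fold (-2.17 ± 0.26) and CEBPB 3.92-fold (-1.97 ± 0.47). DDIT3, a stress-response factor, had a difference of -0.72 ± 0.42 (adjusted p = 0.25), and -1.18 with adjusted p = 0.0167 without control replicate 1, within a range of 0.0167 to 0.625 over 18 alternatives. CALR, an ER chaperone, differed by -0.23 ± 0.42 (adjusted p = 0.736).

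Among 19 measured cholesterol synthesis genes, 7 rose, 0 fell and 12 did not pass (8 rose over the list alone), with a median of 0.75 and camera adjusted p = 0.0299, adjusted p = 0.537 with an estimated correlation. STARD4, a sterol carrier, rose 6.17-fold (2.63 ± 0.24) and INSIG1, a feedback inhibitor of the synthesis, 3.84-fold (1.94 ± 0.27). IDI1 rose 2.72-fold (1.45 ± 0.38) and ACAT2 2.56-fold (1.36 ± 0.34). The list's call was lost without control replicate 1 (median 0.499, adjusted p = 0.0817), without DAMTC replicate 2 (adjusted p = 0.0627), with array weights (0.133) and with detection on all 6 arrays (0.137), within a range of 0.00615 to 0.537 over 19 alternatives. The rises numbered 4 with median scaling (median 0.403) and with the deposited values (0.587), 3 without control replicate 2, and 4, 3 and 2 without DAMTC replicate 1, 2 and 3. Among 10 measured common reference genes, 4 rose, 0 fell and 6 did not pass (4 over the list alone), with a median of 0.80 and camera adjusted p = 0.0299, adjusted p = 0.537 with an estimated correlation. PGK1, TBP (1.24 ± 0.25), B2M (0.97 ± 0.25) and GAPDH (0.89 ± 0.25) rose, and ACTB differed by 0.15 ± 0.25 (adjusted p = 0.709; further probes 0.78 and 0.11). Without PGK1 and GAPDH, which the glycolysis and hypoxia list shares, the 8 genes left had a median of 0.62 with adjusted p = 0.133, an alternative chosen after seeing the data. The list's call was also lost without control replicate 2 (0.0518), without DAMTC replicate 2 (0.0773) and with detection on all 6 arrays (0.0524), within a range of 0.00363 to 0.537 over 20 alternatives. Of the reference genes, 2 rose without DAMTC replicate 1, 2 or 3.

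With the preset correlation, 5 of 36 lists passed, the median of each kept its sign under every background and scaling alternative, and 0 passed with an estimated correlation in camera, where 2 had an unadjusted p under 0.05. Other groupings of the 6 arrays into 3 and 3 gave up to 17 lists with the preset correlation. In at least 1 of those other groupings the adjusted p was smaller than the real one for ER chaperones (7.83e-06), ATF4 targets (3.69e-04), cholesterol synthesis (0.00234) and the common reference genes (0.0266), and larger in each of them for the glycolysis and hypoxia genes (3.72e-07 or more).

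**Figure D2:**
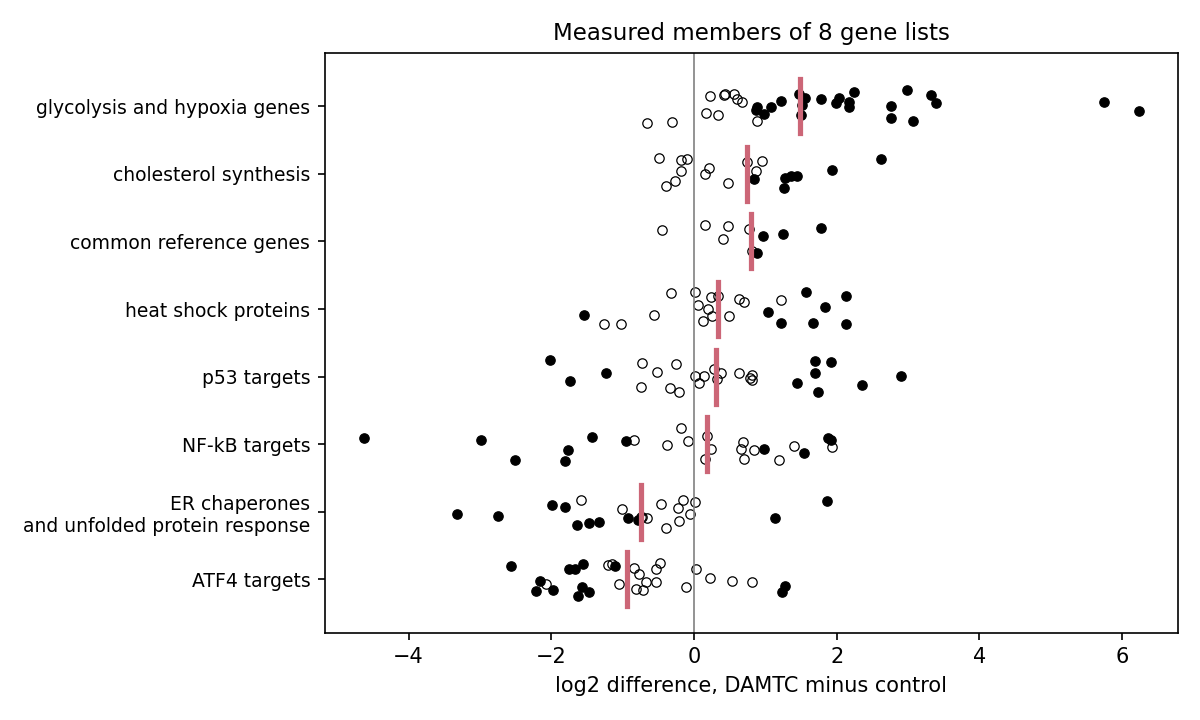
Log2 difference, DAMTC minus control (horizontal axis), of every measured member of 8 gene lists. Filled points passed adjusted p under 0.05, open points did not, vertical red bars are medians, and vertical scatter has no meaning. The median is 1.49 for glycolysis and hypoxia genes and -0.94 for ATF4 targets.

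The remaining 31 tested lists did not pass with the preset correlation (adjusted p from 0.0869 to 0.987). Of the 30 reported here, 13 passed in at least 1 alternative. With fry, which does not set a list against the other genes, 7 of them passed. Upward were p53 targets (adjusted p = 0.00693), pro-apoptotic genes (0.0139) and heat shock proteins (0.0141). Downward were alveolar and lung epithelial markers (0.00205), fatty acid synthesis (0.00808), aryl hydrocarbon receptor targets (0.0141) and ribosome biogenesis (0.0151). Of all 10779 genes tested, 1311 were higher and 1378 lower, 24.95% together. Member counts near these shares, here and in the paragraphs below, do not set a list apart from other genes. Of 23 heat shock proteins, 7 rose and 1 fell (8 and 3 over the list alone), among them HSPA1B (2.13 ± 0.50), HSPA4L (2.13 ± 0.33), BAG3 (1.83 ± 0.24) and DNAJB1 (1.67 ± 0.27), with camera adjusted p = 0.0869. The heat shock list passed in 6 of 19 alternatives, with adjusted p from 0.0141 with fry to 0.581, and 4 of its genes rose without DAMTC replicate 3. Its falls numbered 3 with median scaling or with the deposited values. Of 7 metallothioneins and zinc-responsive genes, MT1X (2.22 ± 0.54; 2.82 without control replicate 3) and the zinc exporter SLC30A1 (2.96 ± 0.30) rose (2 rose and 1 fell over the list alone). Of 26 p53 targets, 7 rose and 3 fell (10 and 3 over the list alone), with PPM1D, a phosphatase, at 2.90 ± 0.28, TP53INP1 at 2.35 ± 0.37, TIGAR at 1.92 ± 0.27 and the DNA repair gene XPC at -2.02 ± 0.27. CDKN1A, a p53 target, differed by 0.38 ± 0.33 (adjusted p = 0.451). Of 23 DNA repair genes, 4 fell and 0 rose (2 fell over the list alone), namely ATM (-2.33 ± 0.23), RAD50 (-2.05 ± 0.36), BRCA1 (-1.29 ± 0.41) and NBN (-1.23 ± 0.35). Falls in this list numbered 2 without control replicate 3 or DAMTC replicate 1, 2 or 3.

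Of 25 NF-kB targets, 7 fell and 4 rose (8 and 7 over the list alone): CXCL2 (-2.99 ± 0.70) and CXCL1 (-2.51 ± 0.77), both chemokines, fell with IL6, and IL1A rose (1.92 ± 0.38; detected on 2 of 3 control arrays). The falls numbered 4 without control replicate 3 or DAMTC replicate 2, and the rises 2 without these or DAMTC replicate 3. With median scaling 2 rose and 8 fell, and with the deposited values 2 and 7. CXCL2 differed by -2.09 and CXCL1 by -1.53 without DAMTC replicate 1, and by -3.66 and -3.36 without DAMTC replicate 3. Of 22 immediate early and MAPK output genes, 5 rose and 4 fell (5 and 4 over the list alone), with the growth factor HBEGF (3.86 ± 0.24), SPRY4 (2.72 ± 0.31) and FOSL1 (1.87 ± 0.28) higher and FOSB (-1.84 ± 0.58; -2.56 without control replicate 2) lower. With median scaling 3 rose and 6 fell, and with the deposited values 3 and 5. The rises numbered 5 without control replicate 1 and 3 without each of the other arrays, and the falls 2 without control replicate 3 or DAMTC replicate 2 and 1 without DAMTC replicate 3. Of 20 interferon-stimulated genes, ISG20 (2.44 ± 0.38), ISG15 (1.81 ± 0.34) and IRF7 (at least 2.07-fold) rose and 0 fell (3 rose over the list alone), while 5 rose and 2 fell without control replicate 1. Of 26 NRF2 targets, 5 fell and 1 rose (5 and 1 over the list alone), with ABCC2 (-1.70 ± 0.30) and AKR1C3 (-1.34 ± 0.27) lower and CBR3 (2.13 ± 0.56; 1.42 without control replicate 1) higher. The falls numbered 3 without DAMTC replicate 1 or 3. HMOX1, an NRF2 target, differed by -0.82 ± 0.32 (adjusted p = 0.0948), and by -1.11 with adjusted p = 0.0127 without control replicate 1, within a range of 0.00244 to 0.282 over 18 alternatives.

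Of 26 pro-apoptotic genes, 8 rose and 3 fell (8 and 3 over the list alone), with BIK (2.64 ± 0.32; detected on 1 of 3 control arrays), BCL2L11 (2.17 ± 0.28; on 2 of 3) and BNIP3 (2.17 ± 0.25), which the hypoxia list shares, higher and FADD (-2.47 ± 0.49) lower. The falls numbered 5 with median scaling or without control replicate 1, and 1 without control replicate 3 or DAMTC replicate 1 or 3. Of 16 anti-apoptotic genes, 2 rose and 3 fell (2 and 4 over the list alone): the decoy receptor gene TNFRSF10D (3.70 ± 0.41) and BAG3 rose, and BIRC6 (-2.02 ± 0.35) and BCL2L1 (-1.84 ± 0.34) were among those that fell, while a second BCL2L1 probe read -0.35 (adjusted p = 0.351). Of 34 autophagy and lysosome genes, 7 rose and 1 fell (7 and 1 over the list alone), with NEU1 (2.56 ± 0.33), ATG4A (1.83 ± 0.33), GABARAPL1 (1.74 ± 0.25) and ATP6V0D1 (1.56 ± 0.24) higher. The rises numbered 4 without DAMTC replicate 1, 2 or 3, and the falls 3 without control replicate 1. With median scaling 4 rose and 3 fell. Of 17 fatty acid synthesis genes, 3 fell and 1 rose (3 and 1 over the list alone), ELOVL6 (-1.77 ± 0.23), MID1IP1 (-1.46 ± 0.43) and ACACA (-1.07 ± 0.23) lower and ACSS2 (1.32 ± 0.28) higher. The falls numbered 5 without control replicate 1 and 1 without DAMTC replicate 3.

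Of 24 tubulins and microtubule regulators, 4 rose and 3 fell (4 and 3 over the list alone), with TUBB2A (3.91 ± 0.33), TUBB3 (2.64 ± 0.49; 3.23 without control replicate 3) and TUBB4B (1.94 ± 0.42) higher and CLIP1 (-1.65 ± 0.31) lower. Further CLIP1 probes read -0.07 (adjusted p = 0.914) and -0.52 (adjusted p = 0.272), and 1 gene of the list fell without control replicate 3 or DAMTC replicate 1. Of 49 actin cytoskeleton genes, PDLIM7 (2.06 ± 0.58; 2.67 without control replicate 3), ARPC4 (1.11 ± 0.26) and TAGLN2 (1.01 ± 0.26) rose and ACTN1 (-0.88 ± 0.25) fell (0 and 0 over the list alone), and further PDLIM7 probes read 0.59 and -0.01. The rises numbered 7 without control replicate 1, 5 without control replicate 3, and at most 1 without control replicate 2, without DAMTC replicate 1 or 3 or with median scaling. Of 12 keratins and intermediate filament genes, KRT80 fell (-1.54 ± 0.30; 1 over the list alone). Of 28 integrin and adhesion genes, 1 rose and 3 fell (1 and 3 over the list alone), with SDC4 at 2.73 ± 0.35, TNS3 at -2.91 ± 0.26, FERMT1 at -0.90 ± 0.25 and LIMS1 lower with adjusted p = 0.0323, further LIMS1 probes reading 1.18 (adjusted p = 0.023), 0.77 (adjusted p = 0.0548) and 0.02 and the mean of its probes 0.243 (adjusted p = 0.511, within a range of 0.0145 to 0.511 over 18 alternatives). The falls of this list numbered 5 without control replicate 1 and 1 without control replicate 3 or DAMTC replicate 2 or 3.

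Of 26 extracellular matrix and protease genes, 3 rose and 5 fell (3 and 8 over the list alone): PLAUR (2.76 ± 0.34), the urokinase receptor, and MMP10 (2.66 ± 0.36; detected on 2 of 3 control arrays) rose, and LAMA5 (-2.69 ± 0.47) and PLAU (-2.47 ± 0.30), urokinase, fell. The falls numbered 2 without DAMTC replicate 2 and 3 without DAMTC replicate 3. With median scaling 2 rose and 9 fell, and with the deposited values 2 and 8, and further PLAUR probes read 2.06 (adjusted p = 0.00307) and 1.12 (adjusted p = 0.0591). Of 15 epithelial junction genes, CLDN1 (-1.84 ± 0.51), CLDN2 (-1.66 ± 0.51) and CDH1 (-1.64 ± 0.43) fell and 0 rose (2 fell over the list alone). CLDN1 differed by -1.18 without control replicate 1 and CLDN2 by -1.05 without control replicate 3. At most 1 of these genes fell without control replicate 3, without any single DAMTC replicate or with no background correction. Of 9 mesenchymal transition genes 0 passed in limma (0 over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05). The smallest p was that of CDH2 (-1.18 ± 0.42, adjusted p = 0.0719), which passed in 3 of 18 alternatives, without DAMTC replicate 1 (-1.67, adjusted p = 0.0122), with median scaling (0.031) and with array weights (0.0111), in a range of 0.0111 to 0.233. SNAI2 (2.17 ± 0.78, adjusted p = 0.0756), detected on 2 of 3 control arrays, passed upward in 4 of 16 alternatives, among them without control replicate 1 (3.22 ± 0.36, adjusted p = 6.63e-04, in a range of 4.71e-04 to 0.196). S100A4 passed upward without control replicate 3 (1.69 ± 0.39, adjusted p = 0.0255), in 1 of 17 alternatives with a range of 0.0255 to 0.724. VIM (0.57 ± 0.23, adjusted p = 0.11) passed upward in 3 of 17, with array weights (0.0321), no background correction (0.0363) and trend and robust moderation (0.0497), in a range of 0.0321 to 0.296. Of 17 TGF-beta targets, 2 rose and 2 fell (3 and 2 over the list alone), with ANGPTL4 at 3.18 ± 0.53, SKI at 0.88 ± 0.26, ID3 at -1.82 ± 0.40 and SMAD6 at -3.90 ± 0.36. With median scaling 1 rose and 4 fell, and with the deposited values 1 and 3. The counts were 4 and 2 without control replicate 1, and 1 and 4 without control replicate 2. A second ANGPTL4 probe read 0.95. Of 19 YAP and TEAD targets, 2 rose and 4 fell (3 and 4 over the list alone), LATS2 (1.43 ± 0.25) higher and AJUBA, NUAK2 (-2.41 ± 0.31) and WWC1 (-1.59 ± 0.25) lower. The falls numbered 7 with median scaling, and the list's median of -0.50 was 0.06 without control replicate 1.

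Of 35 DNA replication genes, 5 rose and 0 fell (4 rose over the list alone), among them CCNE1 (2.64-fold), CDT1 (1.15 ± 0.35), GINS4 (1.02 ± 0.24) and SLBP (1.01 ± 0.26). The rises numbered 3 without control replicate 2 and 1 without DAMTC replicate 1, 2 or 3. With median scaling 2 rose and 1 fell, and with the deposited values 2 and 0. Of 39 mitosis genes, PTTG1 rose (1.77 ± 0.45) and 0 fell (0 over the list alone), and the controls differed widely among themselves. Without control replicate 1, 3 mitosis genes rose, and with median scaling 2 fell. Against the other controls, the mitosis list's median lay at 1.52 in control replicate 1 and at -2.34 in control replicate 2, and the oxidative phosphorylation list's at -0.83 in control replicate 1. Without control replicate 2 the mitosis list passed downward (12 fell, median -0.75, adjusted p = 0.00531, in a range of 0.00531 to 0.983 over 19 alternatives) and ribosomal protein genes upward (0.30, adjusted p = 0.0141, in 0.00742 to 0.893). Without control replicate 3, DNA replication (0.41, adjusted p = 0.0255, in 0.0255 to 0.935), oxidative phosphorylation (0.35, adjusted p = 0.0375, in 0.0375 to 0.94) and proteasome subunits (0.45, adjusted p = 0.0375, in 0.0119 to 0.816) passed upward. These 5 calls were made with the preset correlation. With an estimated correlation in the same fits, chosen after seeing the data, adjusted p was 0.681 for mitosis and for ribosomal protein genes, 0.749 for DNA replication, 0.83 for oxidative phosphorylation and 0.64 for proteasome subunits. No list passed that test in any fit without 1 array, so not passing it does not set these 5 calls apart. Camera's unadjusted p with an estimated correlation was 0.148 to 0.521 for these 5. For the glycolysis and hypoxia list it was 0.00509 to 0.0155 over the fits without 1 array. Of 56 oxidative phosphorylation genes, NDUFS1 fell (-0.98 ± 0.31) and 0 rose (0 over the list alone), while 2 rose with no background correction or with normexp at an offset of 50. Of 68 cytosolic ribosomal protein genes, RPL29 (1.43 ± 0.45) and RPS26 (0.93 ± 0.28) rose and 0 fell (0 over the list alone), and a second RPS26 probe read -0.08. At most 1 rose without control replicate 1 or 2, without any single DAMTC replicate or with median scaling or the deposited values. Of 27 ribosome biogenesis genes, POLR1C (1.07 ± 0.24) rose and RRS1 (-1.99 ± 0.33), POLR1B (at least 1.53-fold lower) and GAR1 (-0.77 ± 0.24) fell (1 and 2 over the list alone). The falls numbered 6 with median scaling or with the deposited values, 5 without control replicate 1 and 1 without DAMTC replicate 1, 2 or 3. Of 29 proteasome subunits, PSMD8 (1.10 ± 0.24) rose and 0 fell (1 over the list alone), while 4 rose without control replicate 1.

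**Figure D3:**
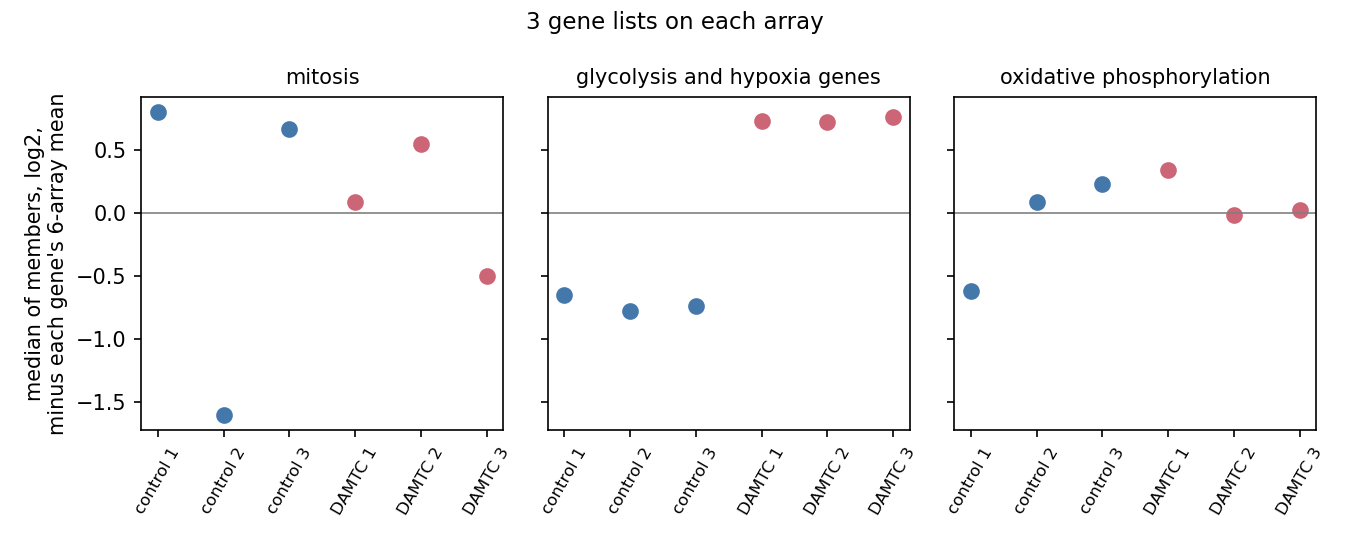
Median over a list's members of the log2 intensity minus each gene's mean over the 6 arrays (vertical axis), for each array, control in blue and DAMTC in red. The mitosis list spans -1.60 to 0.80 within the controls, while the glycolysis and hypoxia list lies between -0.77 and -0.65 in controls and between 0.72 and 0.76 with DAMTC.

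Of 6 aryl hydrocarbon receptor targets, CYP1B1 (-3.80 ± 0.35) and SLC7A5 (-1.63 ± 0.33) fell and 0 rose (2 fell over the list alone), and CYP1A1 was not tested, its probe being detected on at most 1 array. Of 22 drug transport and conjugation genes, 3 rose and 3 fell (3 and 3 over the list alone), with GSTM3 (1.74 ± 0.32; detected on 1 of 3 control arrays) higher and CYP24A1 (-2.28 ± 0.60; -3.02 without control replicate 2), ABCC2 and ABCC4 (-1.29 ± 0.26) lower. Without control replicate 1, 7 of this list fell and 3 rose. In this list 1 rose without control replicate 3 or DAMTC replicate 1, 2 or 3. With median scaling 1 rose and 4 fell, and with the deposited values 1 and 3. Of 7 alveolar and lung epithelial markers, LAMP3 (-2.35 ± 0.71; -1.41 without control replicate 2, detected on 2 of 3 DAMTC arrays) and LPCAT1 (-1.36 ± 0.32) fell and ETV5 (0.82 ± 0.24) rose (2 and 1 over the list alone), and no gene of the list passed without DAMTC replicate 1, 2 or 3. Lists of fibroblast and smooth muscle markers and of leukocyte and endothelial markers had 4 measured members each, too few for the set test, and 0 of them passed in limma (0 over the list alone), while 0 of the first and 3 of the second list had an unadjusted p under 0.05. ACTA2, a smooth muscle actin, differed by -0.65 ± 0.33 (adjusted p = 0.183; -0.92 with adjusted p = 0.0347 without control replicate 1, in a range of 0.0138 to 0.471), and CD68, a macrophage marker, by 1.10 ± 0.37 (adjusted p = 0.0626; 1.41 with adjusted p = 0.0476 without DAMTC replicate 2, in a range of 0.015 to 0.199; a second probe read 0.30 with adjusted p = 0.492).

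Medians, means and tests differed in sign for some lists that did not pass. NF-kB targets had a median of 0.19 and a mean of -0.13, with camera upward and fry downward. TGF-beta targets (median 0.04, mean -0.05) showed the same split. Interferon-stimulated genes (-0.10 and 0.22), immediate early genes (-0.02 and 0.10) and mesenchymal transition genes (-0.06 and 0.20) had a negative median and camera upward, keratins (0.19 and -0.0015) a positive median and camera downward, and anti-apoptotic genes (-0.11 and 0.0096) camera downward. With median scaling the medians of DNA replication (-0.05), mitosis (-0.15), keratins (-0.12), TGF-beta targets (-0.21), autophagy and lysosome genes (-0.05) and fibroblast markers (-0.16) turned negative, each above the -0.26 of all genes. With the deposited values those of mitosis (-0.01), keratins (-0.03), TGF-beta targets (-0.13) and fibroblast markers (-0.06) did, each above -0.19. Leaving out 1 array changed the sign of the median of 12 lists that did not pass. Among these, DNA repair read 0.064 without control replicate 1 and 0.085 without DAMTC replicate 1, metallothioneins -0.082 without DAMTC replicate 1 and interferon-stimulated genes 0.047 without DAMTC replicate 3. Mesenchymal transition genes read up to 0.197, without control replicate 1.

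Of 131 named genes past the threshold, 87 stayed past it in all 6 fits that left out 1 array and 44 were lost in at least 1. Those 44 include CRELD2, HYOU1, CEBPB, IDI1, ACAT2, GAPDH, B2M, CXCL1, CXCL2, FOSB, CBR3, HSPA1B, MT1X, BRCA1, NBN, LIMS1, FERMT1, PDLIM7, ARPC4, TAGLN2, ACTN1, CLDN1, CLDN2, CDH1, LAMP3, LPCAT1, ETV5, CYP24A1, PTTG1, RPL29, RPS26, NDUFS1 and PSMD8. They also include CCNE1, CDT1, GINS4, SLBP, POLR1B, POLR1C, GAR1, MID1IP1, ACACA, SKI and ID3. Calls lost numbered 7, 21 and 23 without control replicate 1, 2 and 3, and 35, 34 and 35 without DAMTC replicate 1, 2 and 3. Each lost call had an adjusted p between 0.0502 and 0.171. Of 40 named genes past the threshold that had further kept probes, 16 had a probe that did not pass. Besides BCL2L1, CLIP1, HYOU1, LIMS1, PDLIM7, PGK1, PLAUR, PRDM1, RORA and RPS26, these were ETV5 (1.10), GAR1 (-0.64), MID1IP1 (-1.26), NBN (-0.90), RPL29 (1.33) and TAGLN2 (0.82), with adjusted p from 0.0511 to 0.123. Of 37 lists, 31 had a count of risen or fallen members that moved by more than 1.5 times in at least 1 of these fits. This number includes moves by only 1 member, unlike the moved counts spelled out per list.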

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

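Probes without exactly 1 gene symbol took no part in the comparison of genes, and a test of them was chosen after the data were seen. In the same limma model, 3247 such probes were detected on at least 3 arrays, and 311 were higher and 309 lower with DAMTC than in controls, 19.1% of them against 24.95% of the named genes. These shares are unlike. Every unnamed probe was counted, with p adjusted over these probes alone, while each named gene was counted by its brightest kept probe. No group held 4 or more arrays, so single arrays were not tested for lying far from the others, and there was 1 contrast, so no pair of effects was compared.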

How the results depend on the processing

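The added tests of common reference genes, of partly detected genes, of the second lists and of an estimated correlation without 1 array were chosen after seeing the data. In 19 alternatives, the glycolysis and hypoxia list and ATF4 targets each lost their call only with the estimated correlation. Where the cause of a change is not given by construction, the cause was not tested. Leaving out 1 array gave 1582 to 3696 changed, 789 to 1710 higher and 793 to 1986 lower genes and 2 to 8 lists. Array weights gave 4864 changed, 2219 higher and 2645 lower. Detection on all 6 arrays at p under 0.01 tested 7412 genes and gave 1702 changed, 822 lower and 2 lists. Adjusted p under 0.01 gave 1279, 672 and 607. Median scaling gave 2144 lower and 8 lists, the deposited values 8 lists, no detection filter 10, fry 11 and the estimated correlation in camera 0 (2 at an unadjusted p under 0.05), and also 0 without any 1 array (1 to 3). The replicate block gave 1588 changed, 764 higher and 824 lower genes and changed no list call. Arrays that share a number deviated apart (r = -0.45, -0.46 and -0.18). With 3 arrays per group these values cannot decide whether samples were handled in pairs, and the labels state no pairing. Of the 2689 genes changed, the refits shared 1554 to 2663, all in the same direction. Direction was compared only for genes called in both fits of largely the same arrays, so this agreement was nearly fixed in advance. Over 35 lists, 594 of 665 list values under an alternative stayed on the same side of the threshold with the same direction, 17 were lost, 26 passed newly and 28 turned. For named genes past the threshold, 2059 of 2324 stayed, 264 were lost and 1 turned.

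The direction of a list's test turned in 28 cases, all but 1 with an adjusted p of 0.455 or more. The exception was mitosis without control replicate 2, with a median of -0.753 and adjusted p = 0.00531. Mitosis turned with array weights (median -0.37), immediate early genes with array weights (-0.33), oxidative phosphorylation with array weights (-0.058) and anti-apoptotic genes with array weights (-0.05). NF-kB targets (0.187) and TGF-beta targets (0.037) turned with fry, and TGF-beta targets also with no detection filter (-0.013). Keratins turned with no background correction (0.155), normexp with offset 50 (0.17), median scaling (-0.118), cyclic loess (0.179), the deposited values (-0.025), the all-array filter (0.529), the mean of probes (0.191), trend and robust moderation (0.191) and the replicate block (0.191). Leaving out 1 array gave medians from -0.138 to 0.413 for DNA replication, -0.753 to 0.597 for mitosis, 0.136 to 0.355 for NF-kB targets and -0.354 to 0.102 for immediate early genes. It gave -0.036 to 0.327 for keratins, -0.205 to 0.35 for TGF-beta targets, -0.009 to 0.348 for oxidative phosphorylation and -0.343 to 0.014 for anti-apoptotic genes, and each of these 8 lists turned in at least 1 such fit. ACTB ranged from -0.016 to 0.267 and CALR from -0.623 to 0.087. CDKN1A turned with array weights (-0.035) and LIMS1 with the mean of its probes (0.243). The second intron-less list turned with the all-array filter (0.098). Dim signal over background limits 7886 genes, which were not tested.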

Other observations

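Further genes that passed the threshold were chosen after their values were seen. HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, fell 3.24-fold (log2 difference -1.70 ± 0.38 SE, n = 3 per group, adjusted p = 0.0127) and EPAS1, its paralog, 1.80-fold (-0.85 ± 0.23, adjusted p = 0.028), while CITED2, which competes with these factors for a coactivator, rose 3.40-fold (1.77 ± 0.28, adjusted p = 0.00283). ARRDC4, an arrestin-domain gene detected on 2 of 3 control arrays, rose 6.85-fold, SLC40A1, the iron exporter, fell 3.06-fold, and the transcription factor genes SOX4 and KLF2 fell 7.43-fold and 5.60-fold. EPAS1 passed in 2 of the 6 fits that left out 1 array (adjusted p up to 0.103) and KLF2 in 5 (up to 0.0505), and the others passed in all 6. The fold of KLF2 was 8.985 without DAMTC replicate 1.

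The tests of scaling, of a swapped sample, of dividing cells, of gene span and of the second lists under alternatives and in camera were chosen only after the result was seen. The others were written before the values they measure were looked at.

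The glycolysis and hypoxia list passed upward with the preset correlation (adjusted p = 0.114 with an estimated correlation). Its median stayed at or above 1.32 whichever array was left out, which argues against 1 array deciding it, and the 14 members that are neither glycolytic enzymes nor glucose or lactate transporters had a median of 1.77, which argues against a scaling of bright glycolytic transcripts. A second list of 31 hypoxia-inducible genes sharing 0 members with the first had 23 measured members, of which 14 rose and 0 fell, with CCNG2 at 2.33 ± 0.27 and FAM162A at 2.91 ± 0.29. Its median of 1.396 lay at percentile 100 of 10000 random lists matched on mean expression, and camera gave unadjusted p = 0.00675 with an estimated correlation, in line with a hypoxia-type transcription programme as a hypothesis. Chip position remains open, and the fall of HIF1A transcripts does not bear on protein.

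Control replicate 1 stood apart from the other controls. Over the 3696 genes called without it, it lay at 0.194 on a scale from the other controls (0) to DAMTC (1), which argues against a swap with a DAMTC sample, and a swap with a sample outside the series was not tested. Its deviations in the brightest and second probe of 2513 genes correlated across genes (Pearson r = 0.745, genes not being independent replicates), which argues against noise of single probes but does not set replicate 1 apart, since control replicate 3 minus 2 gave r = 0.689. The mitosis list's median deviation in it lay at percentile 100 of matched random lists, which takes no account of the list's estimated correlation of 0.8859, so a different share of dividing cells could contribute, but the deviation of control replicate 2 was larger (-2.34 against 1.52), so that this list does not single out replicate 1 and the explanation remains open.

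Some genes known to lack introns were seen among the falls, without a count or a test of how many. A second list of 74 such genes, without those seen among the falls, had 42 measured members, of which 11 fell and 5 rose, and its median of -0.39 lay at percentile 1.1 of matched random lists, a measure that treats genes as independent. Camera gave unadjusted p = 0.0507 with the preset and p = 0.142 with an estimated correlation, and over 14 alternatives the median ranged from -0.751 to 0.098 and the percentile from 0.02 to 69.14. The highest values were those of the 18 members detected on all 6 arrays, of which 4 rose and 4 fell. That filter also removes members that fell out of detection with DAMTC, so a higher median was partly built in. It cannot separate a fall of intron-less transcripts as a class from an effect of dim probes, and both remain open. The list's median level lay at percentile 31.4 of all tested genes. This was to exclude dim probes but does not exclude them, since members below the median can be dimmer. Genes with a span under 5000 bp had a median of 0.002, which argues against short span as such. At the other end, 732 genes with a span over 200000 bp had a median of -0.265, against -0.04 for all genes. Of these long genes 64 rose and 139 fell, and a relation to long span was not tested.

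The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2689 changed, 1311 higher and 1378 lower genes, and was 1 of 10 to reach those counts. The highest other counts in limma were 0, 0 and 0, with 35 to 1149 genes at an unadjusted p under 0.05. Every other split mixes both conditions within each group, so a difference between the conditions widens the spread there and lowers these counts. They are therefore no measure of what chance alone gives. For lists shifted, 7 of the 10 splits gave as many as the 5 of the real one, and the highest other count was 17, with control replicates 1 and 3 and DAMTC replicate 3 together. Counts several times the real one point to a structure of the samples, whose cause was not tested. The glycolysis and hypoxia list passed in 9 of the 9 other splits, with adjusted p down to 3.72e-07 against 8.06e-12, ATF4 targets in 4, ER chaperones in 3 and the cholesterol and reference lists in 2 each, the last 4 lists reaching a smaller adjusted p than in the real split. Each other split leaves 2 arrays of a condition against 1, so treatment and a preset correlation that is too low stay among the open explanations. No correlation was estimated in the other splits.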
